A study of Homo sapiens with 56 samples.

How the data were processed

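Gene expression was measured on 56 Illumina arrays hybridised with RNA from neural progenitor cells derived from the human embryonic stem cell line H9. Per the labels, RNA was extracted with TRIzol and treated with DNase I, and biotinylated cRNA was made with a TotalPrep amplification kit. The submitters' processing notes name GenomeStudio without a version. The authors deposited 1 intensity value per gene symbol and array on a linear scale. These deposited intensity values were background-subtracted, with 23.4% to 24.4% of each array below 0, and quantile-normalized. The sorted values showed 2 sets that had been normalized apart from each other, 1 of the 20 arrays of experiment ND1 and 1 of the 36 arrays of experiments ND2 and NDb. A further deposited table of values before normalization, with 56 columns named by running numbers, was not used, because no label pairs these columns with samples.

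The labels give 28 groups of 2 arrays each. ND1 holds 2 technical replicates of each of 10 conditions, and these pairs were averaged to 1 sample per condition. ND2 holds biological replicates 1 and 2 of the same 10 conditions, and NDb holds biological replicates 3 and 4 of 8 conditions in a reduced medium. The value table had 34687 entries, of which 92 ERCC spike-in entries were left out, leaving 34595. A RefSeq gene table of the assembly GRCh38.p14 was used for names alone: 17757 entries matched a current symbol, 3303 matched a synonym and 13535 matched neither. Symbols are given as deposited, and entries that start with HS. are UniGene clusters.

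Values below 0 were set to 0, 16 was added and log2 was taken. A background bound was set for each normalization set from the spread of the values below 0, at the size that 98% of them do not pass. It was 9.55 intensity units for ND1 and 8.67 for ND2 and NDb. A gene was tested when both arrays of at least 1 group lay above the bound, which left 18373 genes in the optimized medium, 13282 of them named in the RefSeq table, and 17438 in the reduced medium. The number of arrays and the background limit the precision, since array intensities carry no read depth. Each array had between 15817 and 16041 entries above the bound.

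Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. The optimized-medium fit held 30 samples, with 1 coefficient per condition and 1 term for experiment ND1 against ND2. Residual and prior degrees of freedom together came to 25.5 in the optimized medium and 11.1 in the reduced medium. Values below are limma estimates of log2 fold change with their standard error (SE), and group levels are means ± SD over samples on the log2 scale. A fold against a group with every array at or below background was computed against the bound and is given as a lower limit. MLC901 was compared with no treatment at 0, 4, 8, 12 and 24 h, over the mean of 4 to 24 h, and as that mean minus 0 h. Time was tested as each later time minus 0 h within untreated cells, and in the reduced medium as 24 h minus 4 h. The p-values measure only the spread between these samples, which may be technical.

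The comparisons, the rule for named genes and 31 gene lists were fixed before the data were examined. The lists were neural progenitor, early neuronal, synapse and excitability, Notch pathway, astroglia and oligodendroglia, pluripotency, neural crest, mesenchymal and smooth muscle, endoderm and epithelial, and mesoderm, blood and endothelial. They went on with cell cycle G2/M, S phase and replication, immediate early, FGF and ERK feedback, NRF2 and oxidative stress, hypoxia and glycolysis, ER stress and amino acid response, heat shock, cholesterol synthesis, p53 targets, and aryl hydrocarbon receptor and xenobiotic. The remaining lists were metallothionein and metal response, NF-kB and inflammatory, interferon response, neurotrophins and receptors, WNT targets, hedgehog targets, BMP and TGF-beta targets, histones, ribosomal protein, and oxidative phosphorylation. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and the p-values were adjusted over the 31 lists of a comparison. Camera asks whether a list moved against the other genes. Fry asks whether its genes moved, on balance, one way, and its mixed version whether they moved in either direction.

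Named genes were called genes with the same sign in every sample pair, matched by experiment and replicate number. They were the 10 highest and 10 lowest log2 fold changes at 24 h and 5 of each at the other times. Up to 4 called members with the largest absolute change were added per list, or the 2 of highest level where none was called. Where fewer than 3 genes passed, the 5 of smallest p were taken and are said not to pass. BDNF, GDNF, NTRK2, RET and GFRA1 were to be named in the comparison of media. LEF1, SFRP1 and SFRP2 at 24 h were added after their values were seen. Of the genes the rule takes, 2 are not reported here.

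The plan was a single fit of all experiments, but the reduced-medium columns did not match the gene symbols of their table, as the results describe. Each medium was therefore fitted on its own, reduced-medium values were tested without gene names or lists, and the planned comparisons between media were not computed. The planned normalization from unnormalized values with neqc, its normexp, median-scaling and uncorrected variants, a filter on detection p, a block for array slide and a count per probe needed information that the used values do not carry, and were not run. Alternatives that were run changed the log transform, the background filter, array weights, the replicate block, the handling of ND1, the experiment term and the fold minimum, and left out each sample and replicate series. Alternatives added after seeing the data were an offset of 4 or 50, joint quantile normalization of ND1 and ND2, averaging of ND2 replicates, a trended robust prior, removal of the 8 h and 12 h samples of ND2, 1 experiment term per time, and the MLC901 arm in place of the untreated arm. Their effect is given in the closing section.

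The procedure was tested on simulated data with 200 changed genes, 50 at each fold, made from the fitted level and spread of each gene. At 1.5-fold, 98% were recovered for the MLC901 mean of 4 to 24 h, 76% for MLC901 at 12 h, 72% for 24 h minus 0 h, 92% for the reduced-medium mean and 18% for the reduced medium at 12 h. At 2-fold these shares were 100%, 100%, 98%, 98% and 82%. The changes were set on the fitted log2 scale, a 1.5-fold change as 0.585. That scale compresses folds near background, so a gene there needs a larger fold in intensity to change as much. The shares therefore overstate the recovery of intensity folds in genes near background. In the optimized medium each change was set alike in ND1 and ND2, and noise was drawn independently for each gene. The shares do not cover changes that differ between the experiments.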

Results

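Neural progenitor cells made from H9, a human embryonic stem cell line, were profiled as they entered neural differentiation with or without MLC901, a herbal-extract preparation of the NeuroAiD family. The study asked how MLC901 alters gene expression during this step. Cells were sampled at 0, 4, 8, 12 and 24 h in an optimized medium in experiments ND1 and ND2, on 20 arrays each. In ND1 each of the 10 conditions was 1 sample measured on 2 arrays, and in ND2 each had biological replicates 1 and 2, called ND2-1 and ND2-2 here. Experiment NDb, on 16 arrays, used a reduced medium that lacks BDNF, GDNF and anti-oxidants, with replicates 3 and 4 (NDb-3 and NDb-4) at 4 to 24 h. Each optimized condition thus had 3 samples, and each reduced condition had 2. Median intensities were 7.545 to 7.655 units on the ND1 arrays and 6.647 to 6.822 on the others, and 15817 to 16041 entries per array lay above background. The log2 difference between the 2 arrays of a group had a median SD over genes of 0.254 in ND1, 0.215 in ND2 and 0.312 in NDb. Every ND2 pair, labelled biological, differed less (0.187 to 0.236) than every technical ND1 pair (0.242 to 0.295). The spread between the ND2 samples may therefore be technical, and the p-values below may overstate the replication.

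Several abundant genes had close mean levels in ND1 and ND2 and mean levels at background in NDb. TUBB3 and SOX2 lay above background there, at mean log2 levels of 8.35 and 10.1 in NDb against 11.49 and 9.62 in ND2. The cytoskeletal actin gene ACTB had a mean log2 level of 13.95 in ND1, 13.92 in ND2 and 4.25 in NDb. In ND2 and NDb the glycolytic enzyme gene GAPDH had 12.67 and 4.26, the translation factor gene EEF1A1 14.39 and 4.05, the ribosomal protein gene RPLP0 12.38 and 4.15, and VIM, which encodes the intermediate filament protein vimentin, 12.97 and 4.35. Across all genes, which are not independent replicates, mean levels correlated at r = 0.991 between ND1 and ND2 and at r = 0.03 between ND2 and NDb, while arrays within NDb correlated at 0.9787 to 0.993. In 11 of 137 runs of 500 neighbouring entries, NDb levels matched those of ND2 at 1 constant shift of 4543 entries, with r up to 0.991, against at most 0.129 without a shift. The NDb values therefore could not be tied to the gene symbols beside them, and reduced-medium values are given below without gene names. BDNF and GDNF, the factors left out of that medium, lay above background on 0 of 40 optimized-medium arrays. Their receptor genes lay above it on 4 arrays (NTRK2), 19 arrays (RET) and 34 arrays (GFRA1).

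**Figure D1:**
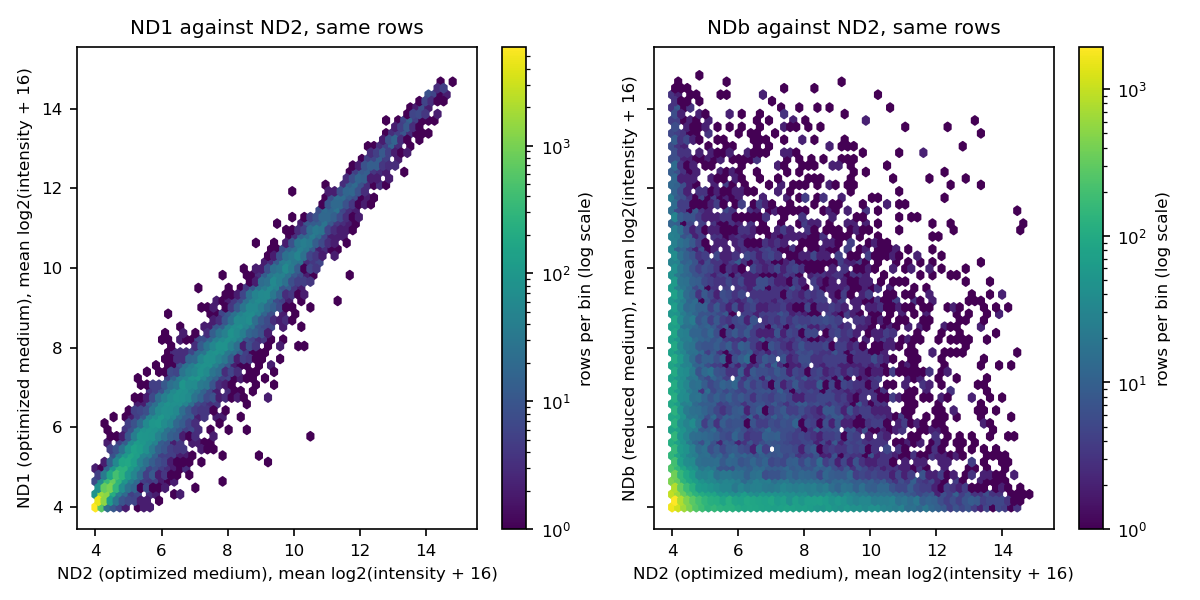
Mean log2(intensity + 16) of each entry of the value table in ND1 (left) and NDb (right) against ND2, as bins coloured by the number of entries on a log scale. ND1 follows ND2 along the diagonal (r = 0.991) and NDb does not (r = 0.03).

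The time course asked which genes changed as untreated progenitors differentiated. By 4 h several WNT target genes had fallen together with FGF19, and SHISA2, CTGF, PGF and CD248 had risen. FGF19, which encodes a secreted fibroblast growth factor, was 5.15-fold lower at 4 h than at 0 h (8.28 ± 0.20 to 5.91 ± 0.29, SD, n = 3; SE 0.129; adjusted p = 3.09e-12). SHISA2, which encodes a membrane protein that restrains WNT and FGF receptors, was 4.87-fold higher (6.35 ± 0.77 to 8.64 ± 1.28, SD, n = 3; SE 0.223; adjusted p = 1.19e-07). CTGF, a matricellular growth factor gene now named CCN2, rose 3.25-fold (SE 0.242), the placental growth factor gene PGF 2.94-fold (SE 0.181) and CD248, a stromal surface glycoprotein gene, 2.77-fold (SE 0.10). SP5, a direct WNT target, fell from 6.66 to a mean of 4.43 near background, above which 2 of 4 arrays lay. NKD1, a WNT feedback inhibitor gene, fell by 1.98 on the log2 scale (SE 0.141), and CYP1B1, a cytochrome P450 gene, fell by 2.17 (SE 0.142). TFRC, the transferrin receptor gene, was 4.49-fold lower at 4 h (SE 0.140; adjusted p = 1.13e-10). THBS1, the thrombospondin gene, rose 2.97-fold (SE 0.292; adjusted p = 0.000975), a call lost without series ND2-1 (adjusted p = 0.0886) or ND2-2 (adjusted p = 0.142) and with ND2 replicates averaged (adjusted p = 0.0871).

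The WNT target list moved down at 4 h and stayed down. Of its 23 tested members, 11 fell and 1 rose at 4 h (14 and 2 adjusted over the list alone), with a median log2 fold change of -0.506 and a camera adjusted p of 1.37e-15 (adjusted p = 4.11e-06 with an estimated correlation). AXIN2, a feedback inhibitor gene widely used as a readout of beta-catenin signalling, was 3.52-fold lower at 4 h (SE 0.154) and APCDD1, another WNT inhibitor gene, was 2.97-fold lower (SE 0.126). At 8 h 12 members fell and 3 rose (14 and 5 adjusted over the list alone; median -0.546; adjusted p = 1.18e-06, and adjusted p = 0.00159 with an estimated correlation). At 12 h 13 fell and 3 rose (15 and 4 adjusted over the list alone; median -0.689; adjusted p = 6.12e-09, and adjusted p = 0.000209 with an estimated correlation). At 24 h 12 fell and 3 rose (15 and 4 adjusted over the list alone; median -0.620; adjusted p = 3.69e-08, and adjusted p = 0.000227 with an estimated correlation). The 24 h list median was -0.530 in ND1, -0.757 in ND2-1 and -0.835 in ND2-2. At that time AXIN2 was 3.25-fold lower, NKD1 5.22-fold lower and APCDD1 5.04-fold lower, and SP5 was at least 4.06-fold lower, being at background on all arrays. Members chosen after their values were seen were LEF1, a WNT-responsive transcription factor gene, at a log2 fold change of -1.33 (SE 0.098), and SFRP1 and SFRP2, genes of secreted WNT antagonists, at 0.95 (SE 0.121) and 1.17 (SE 0.089).

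**Figure D2:**
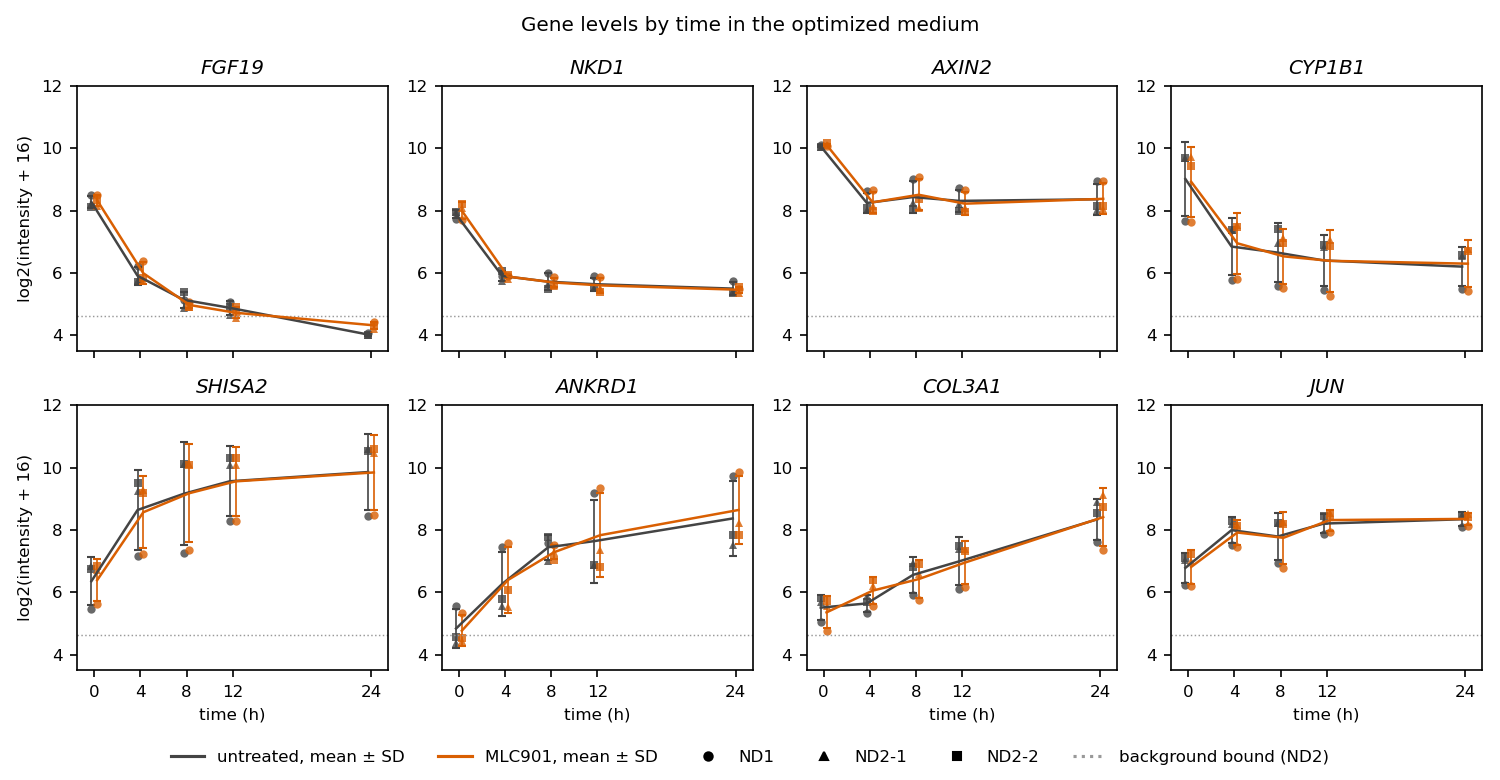
Log2(intensity + 16) of 8 genes by time in h in the optimized medium, untreated in grey and MLC901 in orange. Points are samples (circle ND1, triangle ND2-1, square ND2-2), lines are means with SD over 3 samples, and the dotted line is the background bound of ND2; FGF19, NKD1, AXIN2 and CYP1B1 go down with time, SHISA2, ANKRD1, COL3A1 and JUN go up, and the 2 treatment lines lie close together.

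Genes of the extracellular matrix and contractile apparatus rose over the following hours. Of the 18 tested members of the mesenchymal and smooth muscle list, 3 rose at 4 h, 10 at 8 h, 13 at 12 h and 14 at 24 h, and 0 fell over all genes tested. Adjusted over the list alone these counts were 5, 10, 14 and 14, with 1 member lower at 24 h. The list median was 0.262 at 4 h (adjusted p = 3.32e-06; adjusted p = 0.0157 with an estimated correlation) and 0.450 at 8 h (adjusted p = 2.38e-06; adjusted p = 0.0161 with an estimated correlation). It was 0.652 at 12 h (adjusted p = 2.49e-13; adjusted p = 0.000209 with an estimated correlation) and 0.984 at 24 h (adjusted p = 3.07e-19; adjusted p = 3.66e-05 with an estimated correlation). COL3A1, a fibrillar collagen gene, was 7.14-fold higher at 24 h (5.50 ± 0.41 to 8.34 ± 0.66, SD, n = 3; SE 0.165; adjusted p = 3.54e-12) and COL1A1 3.38-fold higher (SE 0.185). TAGLN, an actin-binding smooth muscle protein gene, rose 4.61-fold (SE 0.231), and ANXA1, an annexin gene, 3.55-fold (SE 0.196). PDGFRB, a platelet-derived growth factor receptor gene, was already 2.77-fold higher at 4 h (SE 0.137). The 24 h median was 1.08 in ND1, 0.774 in ND2-1 and 0.808 in ND2-2. COL6A3, FBN1, S100A4 and THY1 were not called at 24 h, with log2 fold changes of -0.19, 0.29, 0.25 and 0.23.

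Among named genes the largest rise at 24 h was that of ANKRD1, a target gene of YAP signalling, at 11.6-fold (4.83 ± 0.63 to 8.37 ± 1.19, SD, n = 3; SE 0.346; adjusted p = 3.63e-08), followed by SHISA2 at 11.3-fold (SE 0.223; adjusted p = 2.28e-11). The 0 h level of ANKRD1 lay near background, where folds are compressed. Over both arms ANKRD1 rose more in ND1 than in ND2, by 0.98 on the log2 scale, and SHISA2 less, with a difference of -0.83. ACTG2, the enteric smooth muscle actin gene, rose 5.84-fold (SE 0.199), CYR61, a matricellular gene now named CCN1, 4.58-fold (SE 0.290), and HAPLN1, a hyaluronan link protein gene, 4.57-fold (SE 0.150). CTGF was 4.29-fold higher (SE 0.242) and THBS1 3.77-fold (SE 0.292). At the other end, FGF19 was at least 12.4-fold lower (8.28 ± 0.20 to 4.02 ± 0.04, SD, n = 3; adjusted p = 3.72e-18), C11ORF87 at least 6.10-fold lower and the ADAMTS-like gene ADAMTSL2 at least 3.17-fold lower, all of them at background on every 24 h array. CYP1B1 was 7.02-fold lower (SE 0.142), and RGS4, a regulator of G-protein signalling, fell by 2.38 on the log2 scale (SE 0.376). EGR2, an early growth response gene, fell by 1.86 (SE 0.279).

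Of the 23 tested immediate early genes, 8 rose and 1 fell at 4 h (9 and 2 adjusted over the list alone; adjusted p = 1.64e-05, and adjusted p = 0.0336 with an estimated correlation). JUN, a subunit of the AP-1 transcription factor, rose 2.31-fold at 4 h (SE 0.159) and 2.95-fold at 24 h (SE 0.159). EGR1, another early growth response gene, fell by 1.49 at 4 h (SE 0.312; adjusted p = 0.00311), a call lost without ND2-1 (adjusted p = 0.0955) or ND2-2 (adjusted p = 0.0687) and with ND2 replicates averaged (adjusted p = 0.065). At 24 h 9 members rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.00322), and adjusted p = 0.178 with an estimated correlation. The list also passed at 8 h (8 up and 2 down, or 9 and 2 adjusted over the list alone; adjusted p = 0.0428) and 12 h (8 up and 2 down, or 8 and 4 adjusted over the list alone; adjusted p = 0.021), with adjusted p = 0.444 and adjusted p = 0.42 with an estimated correlation. Among 19 tested NF-kB and inflammatory genes, 5 rose and 0 fell at 4 h, over all genes and adjusted over the list alone (adjusted p = 0.00657, and adjusted p = 0.0377 with an estimated correlation). The same counts held at 24 h (adjusted p = 0.0128, and adjusted p = 0.0765 with an estimated correlation). VCAM1, a vascular adhesion molecule gene, rose 2.28-fold by 24 h (SE 0.160) and the interferon-regulated transcription factor gene IRF1 1.62-fold (SE 0.096). Of 22 interferon response genes 7 rose and 2 fell at 24 h (8 and 2 adjusted over the list alone; adjusted p = 0.0239, and adjusted p = 0.181 with an estimated correlation). IFIT1 and IFITM1, both interferon-induced antiviral genes, were 2.43-fold (SE 0.093) and 2.03-fold (SE 0.148) higher.

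Mitotic genes were higher at 8 h. Of 30 tested cell cycle G2/M genes 18 rose and 0 fell (24 and 2 adjusted over the list alone; median 0.421; adjusted p = 3.62e-08, and adjusted p = 0.195 with an estimated correlation). HMMR, a spindle-associated hyaluronan receptor gene, rose 1.65-fold at 8 h (SE 0.119), a call lost at a log2 fold change of 0.364 (adjusted p = 0.157) without the 8 h and 12 h samples of ND2, which leaves ND1 as the only 8 h sample. At 12 h 12 members rose (13 adjusted over the list alone; adjusted p = 4.86e-05, and adjusted p = 0.43 with an estimated correlation), and at 24 h 5 rose (7 adjusted over the list alone; adjusted p = 0.00322, and adjusted p = 0.574 with an estimated correlation). Among 36 oxidative phosphorylation genes 12 fell at 8 h, 6 at 12 h and 2 at 24 h (17, 6 and 2 adjusted over the list alone, beside 1, 0 and 0 that rose). Camera gave adjusted p = 2.74e-05, 0.00167 and 0.0443, and adjusted p = 0.444, 0.601 and 0.817 with an estimated correlation. The 8 h median was 0.029 in ND1, -0.438 in ND2-1 and -0.433 in ND2-2. CYCS, the cytochrome c gene, fell by 0.54 on the log2 scale at 8 h (SE 0.090). Of 34 ribosomal protein genes 7 fell and 1 rose at 8 h, over all genes and adjusted over the list alone (adjusted p = 0.0428, and adjusted p = 0.539 with an estimated correlation), with medians of 0.026 in ND1, -0.218 in ND2-1 and -0.213 in ND2-2. Heat shock genes had 4 of 21 up and 1 down at 8 h (6 and 1 adjusted over the list alone; adjusted p = 0.0489, and adjusted p = 0.444 with an estimated correlation), with HSPA1A 2.00-fold higher (SE 0.113) and HSPA1L 1.71-fold higher (SE 0.089), and list medians of -0.102 in ND1, 0.183 in ND2-1 and 0.264 in ND2-2. Pluripotency genes had 3 of 10 up at 8 h (4 adjusted over the list alone; adjusted p = 0.0428, and adjusted p = 0.195 with an estimated correlation), with medians of 0.175 in ND1, 0.442 in ND2-1 and 0.517 in ND2-2.

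**Figure D3:**
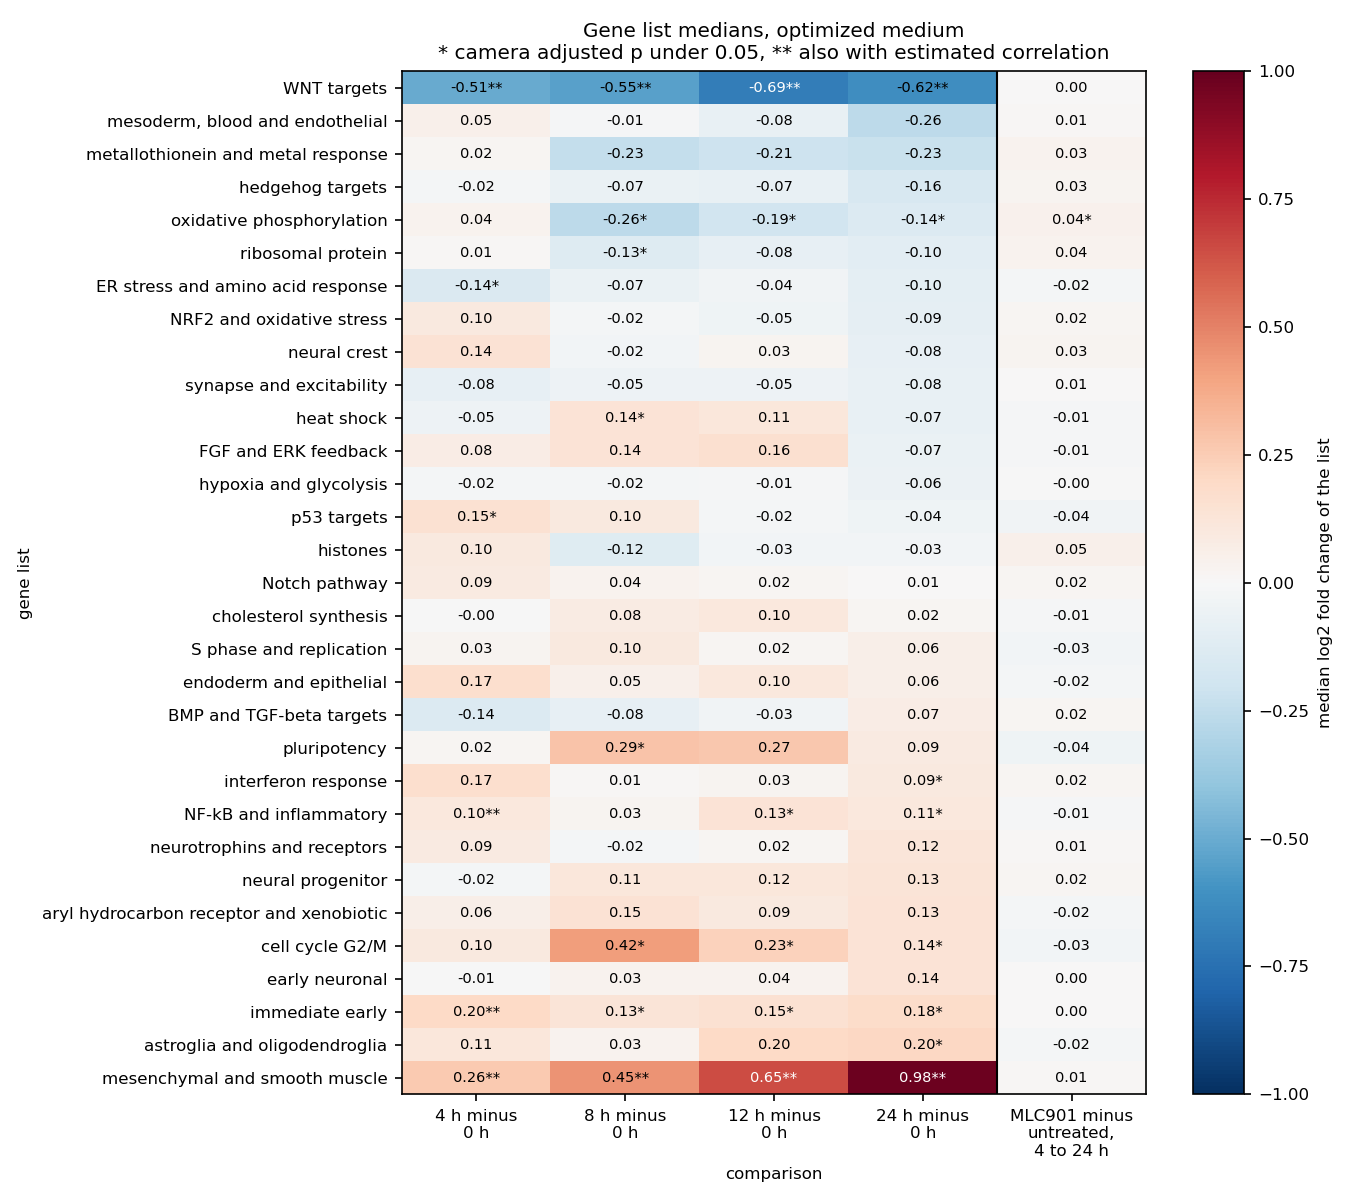
Median log2 fold change of each of the 31 gene lists (vertical) at 4, 8, 12 and 24 h minus 0 h in untreated cells and for MLC901 minus untreated over 4 to 24 h (horizontal), coloured from -1 to 1. Stars give camera adjusted p under 0.05, with a pair of stars where the call held with an estimated correlation; WNT targets are the lowest and the mesenchymal list the highest at 24 h.

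Neuronal lineage genes moved both ways at 24 h. Of 33 early neuronal genes 6 rose and 5 fell (10 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.151). ISL1, a motor neuron transcription factor gene, rose 1.89-fold (SE 0.130) and DCX, the microtubule protein gene of migrating neuroblasts, 1.74-fold (SE 0.102). Of 24 neural progenitor genes 10 rose and 4 fell (11 and 8 adjusted over the list alone; adjusted p = 0.242). PAX6, a transcription factor gene of neural progenitors, rose from 4.61, with 1 of 4 arrays above background, to 5.52, a log2 difference of 0.903 that was 0.443, still called, without ND1. MEIS2, a homeobox gene, rose 1.79-fold (SE 0.078), and SLC1A3, a glutamate transporter gene of radial glia, fell by 0.77 on the log2 scale (SE 0.125). HES5, a Notch effector gene, had a 3.96-fold higher mean (SE 0.596; adjusted p = 0.0248), with log2 differences of 4.41 in ND1, 0.61 in ND2-1 and 0.94 in ND2-2. That call was lost without series ND2-1 (adjusted p = 0.0582), without ND2-2 (0.0948), without the ND1 sample at 24 h (0.177) and without the ND1 sample at 0 h (0.202). Without ND1 altogether the log2 difference was 0.774 and called. Glial genes had 3 of 11 up (3 adjusted over the list alone; adjusted p = 0.0443, and adjusted p = 0.181 with an estimated correlation), with the gap junction gene GJA1 2.25-fold (SE 0.178) and the growth factor receptor gene PDGFRA 2.07-fold (SE 0.105) higher.

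At 4 h limma called 1112 of 18373 genes, 596 higher and 516 lower than at 0 h, 219 and 130 of them by at least 1.5-fold. Among 32 ER stress and amino acid response genes 6 fell at 4 h (11 adjusted over the list alone; adjusted p = 4.98e-04, and adjusted p = 0.0925 with an estimated correlation), and HSPA5, the gene of the ER chaperone BiP, was 1.53-fold lower (SE 0.080). Among 24 p53 targets 1 rose and 1 fell, over all genes and adjusted over the list alone (adjusted p = 0.0191, and adjusted p = 0.0694 with an estimated correlation). The 4 h count was 207 without ND2-1, 193 without ND2-2, 668 and 687 without the 4 h sample of ND2-1 or of ND2-2, and 730 without the 0 h sample of ND2-1. It was 1762 with 1 experiment term per time, a setting chosen after seeing the data, and 1881 with array weights. With no experiment term 192 genes passed and 43 named genes lost their call. SHISA2 (adjusted p = 0.408), CYP1B1 (adjusted p = 0.204), PDGFRB (adjusted p = 0.129) and JUN (adjusted p = 0.16) did not pass. Each condition holds the same mix of experiments, so at 4 to 24 h this setting leaves the folds of the named genes as printed and adds the difference between ND1 and ND2 to the error.

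At 8 h the extremes were SHISA2, 6.98-fold higher (SE 0.223), ANKRD1, 6.10-fold higher (SE 0.346), and the lipoprotein lipase gene LPL, 4.15-fold higher (SE 0.205). CTGF rose 4.05-fold (SE 0.242) and THBS1 3.90-fold (SE 0.292). These rises average ND1 and ND2, which differed at 8 h. Over both arms SHISA2, LPL, CTGF and THBS1 rose less in ND1, with log2 ND1 minus ND2 differences of -1.55, -1.35, -1.62 and -1.97. The difference for ANKRD1 (-0.70) was not called by limma (adjusted p = 0.0611). FGF19 was 8.80-fold lower (SE 0.129), NKD1 4.47-fold lower (SE 0.141), CYP1B1 5.14-fold lower (SE 0.142), C11ORF87 3.93-fold lower (SE 0.154), and SP5 fell to a level near background, with 1 of 4 arrays above it. At 8 h 4393 genes were called, 2158 higher and 2235 lower, 545 and 487 of them by at least 1.5-fold. The count was 6616 without ND1, 906 without ND2-1 and 757 without ND2-2. It was 2482 and 2388 without the 8 h sample of ND2-1 or of ND2-2, and 2758 and 2687 without their 0 h samples. Without the 8 h and 12 h samples of ND2 it was 628, and THBS1 was no longer called at a log2 fold change of 0.819 (adjusted p = 0.114). That setting leaves 1 sample at 8 h and 1 at 12 h, both of ND1, whose spread is taken from the other groups. The count was 7489 with 1 experiment term per time and 7207 with array weights. With no experiment term it was 851, and 74 named genes were no longer called. Among them were SHISA2 (adjusted p = 0.0763), CYP1B1 (adjusted p = 0.0533) and CYCS (adjusted p = 0.129).

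At 12 h SHISA2 was 9.22-fold higher (SE 0.223), ANKRD1 6.99-fold (SE 0.346), the peptide transporter gene SLC15A3 3.97-fold (SE 0.195), CTGF 3.90-fold (SE 0.242) and THBS1 3.74-fold (SE 0.292). FGF19 was 10.5-fold lower (SE 0.129), CYP1B1 6.12-fold (SE 0.142), C11ORF87 5.25-fold (SE 0.154) and NKD1 4.73-fold (SE 0.141) lower, and SP5 again had 1 of 4 arrays above background. In all 3083 genes were called, 1565 higher and 1518 lower, 484 and 342 of them by at least 1.5-fold. Of the NF-kB list 5 members rose and 0 fell at 12 h, also adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.11 with an estimated correlation). The count was 704 without ND2-1, 834 without ND2-2, 1818 without the 12 h sample of ND2-1, and 1985 and 1934 without the 0 h sample of ND2-1 or of ND2-2. It was 4969 with 1 experiment term per time and 7102 with array weights. With no experiment term it was 533, and 69 named genes lost their call. Among them were SHISA2 (adjusted p = 0.054) and SLC15A3 (adjusted p = 0.269).

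At 24 h 2663 genes were called, 1423 higher and 1240 lower, 534 and 314 of them by at least 1.5-fold. In the MLC901 arm the same comparisons called 607 higher and 490 lower genes at 4 h, 1845 and 1846 at 8 h, 1178 and 1040 at 12 h, and 1463 and 1428 at 24 h. The 24 h count of the untreated arm was 1021 without ND2-1 and 964 without ND2-2. With no experiment term 562 genes passed and 70 named genes lost their call. TAGLN (adjusted p = 0.116), HAPLN1 (adjusted p = 0.185), ANXA1 (adjusted p = 0.233) and HES5 (adjusted p = 0.351) did not pass, nor did SFRP2 (adjusted p = 0.141), GJA1 (adjusted p = 0.118), IRF1, PAX6, IFITM1, PDGFRA, VCAM1, DCX and ISL1 (adjusted p from 0.216 for IRF1 to 0.919 for ISL1).

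**Figure D4:**
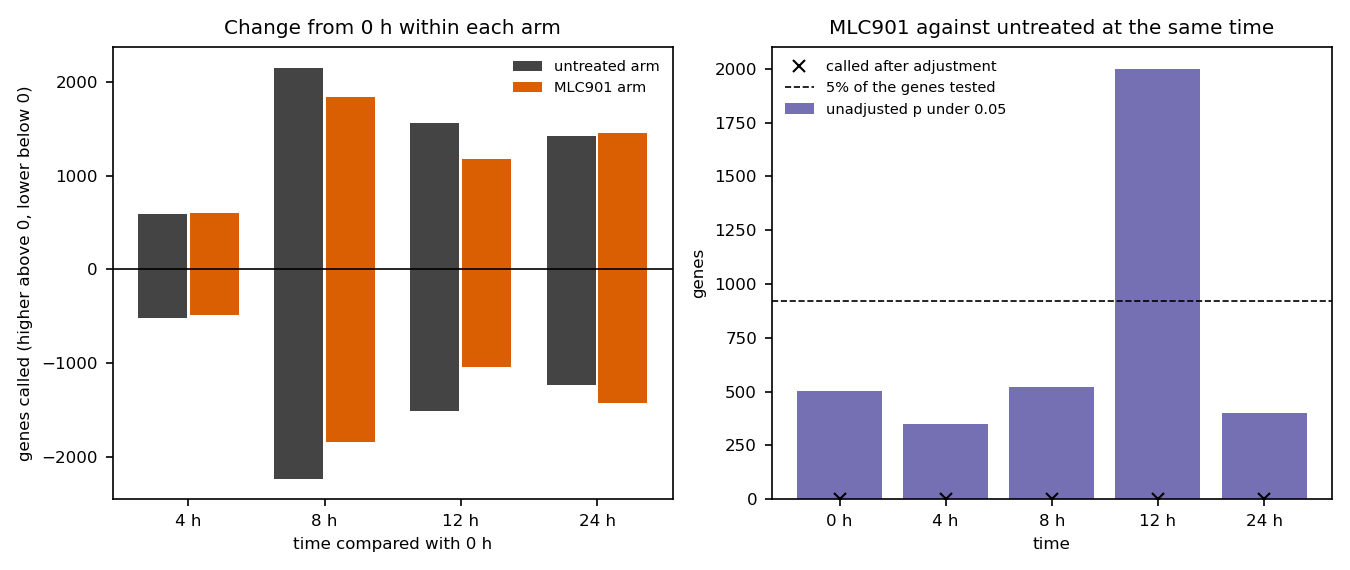
Left, number of genes called higher (above 0) or lower (below 0) than at 0 h by time in the untreated arm (grey) and the MLC901 arm (orange). Right, number of genes at unadjusted p under 0.05 for MLC901 against untreated at each time (bars), with the number called after adjustment (crosses, 0 at each time) and 5% of the genes tested (dashed line).

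The comparison of MLC901 with untreated cells asked which genes the extract altered. No gene was called in the optimized medium at any time or over the mean of 4 to 24 h with 1 experiment term for all times. With 1 term per time, 2 genes were called over the mean, LOC100132673 (log2 difference 0.334, SE 0.049; adjusted p = 0.0211) and LOC440063 (0.432, SE 0.069; adjusted p = 0.0365). With 1 term for all times, the smallest p-values over the mean belonged to LOC440063 and to PLIN5, which encodes a lipid droplet protein. LOC440063 stood at 10.66 without and 11.09 with MLC901 (log2 difference 0.43, SE 0.083, n = 12 samples per arm, adjusted p = 0.363). PLIN5 stood at 7.58 and 7.24 (log2 difference -0.34, SE 0.069, adjusted p = 0.363). Each kept its sign in 3 of 3 sample series, although replicate numbers did not pair the ND2 samples. LOC646836 (0.19), LOC647030 (0.22) and LOC729010 (-0.19) followed, at adjusted p = 0.626 or above. At 12 h the genes of smallest p were LDB1, a LIM-domain cofactor gene (0.51, SE 0.110), WWC2 (-0.42, SE 0.093), HS.156892 (-0.41), PLIN5 (-0.58, SE 0.138) and the protein disulfide isomerase gene PDIA5 (0.31, SE 0.074), and none passed (lowest adjusted p = 0.452).

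The labels do not say how long the 0 h MLC901 cells had been with MLC901, so the exposure behind the 0 h comparison and behind the mean minus 0 h is not known. At 0 h the smallest p-values belonged to LMAN2, a lectin gene of the secretory pathway (log2 difference 0.51, SE 0.124), LDB1 (0.43, SE 0.110), HS.542805 (0.59), LOC652183 (0.45) and LOC649318 (0.55), at a lowest adjusted p of 1. At 4 h they belonged to PLIN5 (-0.66, SE 0.138), LOC650885 (0.52), LOC730704 (0.48), LOC728924 (-0.51) and LOC644000 (0.44; lowest adjusted p 1). At 8 h they belonged to MORC4 (-0.50, SE 0.108), HS.544434 (0.67), HS.501656 (0.62), LOC286467 (0.38) and HS.145039 (0.61; lowest adjusted p 0.793). At 24 h they belonged to the zinc finger gene ZNF714 (0.44, SE 0.097), FAM129C (-0.53, SE 0.124), ANKRD19 (0.56), RNF152 (0.35) and LOC284648 (-0.50; lowest adjusted p 1). For the mean minus 0 h, WWC2 had the smallest p (-0.51, SE 0.105; adjusted p 0.961), followed by 4 UniGene clusters.

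Of the gene lists, oxidative phosphorylation was called higher with MLC901 by camera at 8 h (median 0.078; adjusted p = 0.0403, and adjusted p = 0.867 with an estimated correlation), at 12 h (median 0.118; adjusted p = 0.000938, and adjusted p = 0.905 with an estimated correlation) and over the mean (median 0.044; adjusted p = 0.00433, and adjusted p = 0.89 with an estimated correlation). Its 36 members had 0 called genes, over all genes tested and adjusted over the list alone. Cell cycle G2/M was called lower at 12 h (median -0.148; adjusted p = 0.00189, and adjusted p = 0.905 with an estimated correlation), with medians of 0.062 in ND1, -0.355 in ND2-1 and -0.073 in ND2-2. The 12 h oxidative phosphorylation median was 0.025 in ND1, 0.326 in ND2-1 and 0.042 in ND2-2. Fry called 0 lists in these comparisons, and camera 0 at 0, 4 and 24 h. Without ND2-1 camera called 0 lists at 8 h, at 12 h and over the mean, and at 12 h it also called 0 without the MLC901 or the untreated sample of ND2-1. At 8 h it called 0 without ND2-2, without the ND1 or ND2-1 sample with MLC901 and without either untreated ND2 sample, 2 without ND1 or the MLC901 sample of ND2-2, and 3 without the untreated ND1 sample. Over the mean it called 3 without ND1 and 2 without ND2-2, and it called 1 list at 0 h without the MLC901 sample of ND1, 1 at 4 h without the untreated ND1 sample, and at 24 h 1 and 2 without the MLC901 or the untreated ND1 sample.

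Limma gave 502, 349, 523, 2002 and 398 genes at an unadjusted p under 0.05 at 0, 4, 8, 12 and 24 h, 1115 over the mean and 486 for the mean minus 0 h, where 5% of the genes tested is 919. The median 95% half-width was 0.249 on the log2 scale at 1 time and 0.125 over the mean. On that scale, which compresses folds near background, the interval of the mean lay inside 1.5-fold in either direction for 18370 of 18373 genes. At 12 h the interval lay inside 1.5-fold for 16623 genes. Larger folds in intensity are not excluded for genes near background. The mean MLC901 difference of ND1 correlated with that of ND2 at r = -0.00972 and rho = -0.0152 across genes, which are not independent replicates, and 79 of 100 permutations of the treatment labels gave a correlation as large (permutation p = 0.79). A test of the difference between ND1 and ND2 in the MLC901 effect called 0 genes at each time with limma, with 384, 436, 530, 2075 and 547 at an unadjusted p under 0.05. Without ND1, 1419 genes were called at 12 h and 1 at 8 h (LOC645662, chosen after its values were seen), and without the MLC901 sample of ND1 at 8 h 1 was called. With array weights, which gave ND1 samples a median weight of 0.681 and ND2 samples 1.16, 642 genes were called at 8 h, 1537 at 12 h and 55 over the mean. Single ND2 samples carried weights of 7.66 at 8 h and 6.31 at 12 h, where the lowest ND2 weights were 0.523 and 0.429, so these counts lean on 1 sample at each time.

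In the reduced medium, whose values could not be given gene names, MLC901 and untreated cells were compared over 17438 entries with 2 samples per condition. Limma called 0 entries at 4, 8, 12 and 24 h and 0 over the mean, with 721, 654, 1278, 968 and 846 at an unadjusted p under 0.05, where 5% of those tested is 872. The planned single fit of all experiments gave 160, 126, 345 and 265 entries at these times and 146 over the mean. That fit takes the spread of an entry partly from ND1 and ND2 values that could not be tied to the same gene. Its counts therefore cannot be read as MLC901 effects. In the fit of the reduced medium alone the lowest adjusted p was 0.174, at 12 h. The median 95% half-width there was 0.359 on the log2 scale at 1 time and 0.18 over the mean. On that scale, which compresses folds near background, the interval of the mean lay inside 1.5-fold for 16805 entries. Between 4 h and 24 h in untreated cells 970 entries were called, 416 higher and 554 lower at 24 h, 252 and 329 of them by at least 1.5-fold. That count was 256 without the 24 h sample of NDb-3, 237 without that of NDb-4, 306 without the 4 h sample of NDb-3 and 141 without that of NDb-4. For MLC901, leaving out the untreated 12 h sample of NDb-4 gave 23 entries at 12 h, and leaving out the MLC901 24 h sample of NDb-4 gave 1 at 24 h.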

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

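The comparison of time changes between ND1 and ND2, the test of a sample state and both tests of the gene order were chosen after the results were seen. The tests of a shared MLC901 effect and of gene span were written before.

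The change from 0 h differed between ND1 and ND2 in tests of the difference itself, over both arms. At 4 h 94 genes differed, at 8 h 4273, at 12 h 519 and at 24 h 1611, of which 68, 1817, 313 and 773 differed by at least 1.5-fold. Of the 25 genes named for the extremes of the time course, 7, 16, 14 and 14 differed at these times. HES5 rose more in ND1, by 3.11 on the log2 scale at 8 h and 3.51 at 24 h. The change of RGS4 from 0 h was lower in ND1, by an ND1 minus ND2 difference of -2.10 at 8 h and -1.98 at 24 h. The matricellular genes THBS1, CYR61 and CTGF rose less in ND1 at 8 h, with differences of -1.97, -1.88 and -1.62. So did SHISA2, with -1.55, and LPL, with -1.35. At 24 h EGR2 differed by -1.62, ACTG2 by -1.29, TAGLN by -1.26 and HAPLN1 by -0.93. Of the gene lists, 3, 1, 2 and 6 differed at 4, 8, 12 and 24 h with the preset and the estimated correlation. For these lists, higher or lower in ND1 refers to the change from 0 h and not to the level. FGF and ERK feedback genes were lower in ND1 at 8 h (median difference -0.517; adjusted p = 6.17e-06, and adjusted p = 0.00186 with an estimated correlation) and at 24 h (-0.421; adjusted p = 1.61e-05, and adjusted p = 0.00272 with an estimated correlation). Notch pathway genes were higher in ND1 at 24 h (0.302; adjusted p = 7.97e-06, and adjusted p = 0.00613 with an estimated correlation). Neural progenitor genes were higher in ND1 at 12 h (0.064; adjusted p = 0.0247 with an estimated correlation) and 24 h (0.179; adjusted p = 0.00642), as were metallothionein (0.087) and neurotrophin genes (0.291) at 24 h, while heat shock genes were lower (-0.273; adjusted p = 0.0387 for these 3 lists). FGF and ERK feedback genes were also lower at 4 h (-0.097; adjusted p = 0.0405) and 12 h (-0.397; adjusted p = 0.00313), as were mesenchymal (-0.14; adjusted p = 0.0443) and hypoxia genes (-0.055; adjusted p = 0.0405) at 4 h. ND1 holds 1 sample per condition, and it was normalized apart from ND2, so that experiment and normalization set cannot be separated.

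At 12 h ND2 alone called 1419 genes between MLC901 and untreated cells, 683 higher and 736 lower. An effect shared by both experiments was argued against, since the median ND1 change of these genes was -0.0575 times that of ND2 and 40.5% of them moved in the ND2 direction in ND1. A state of single ND2 samples that does not follow treatment cannot be told apart from one that does. The untreated ND2 samples at 12 h differed along the excess of ND2 over ND1 at 8 h (r = 0.414 across genes, which are not independent replicates). Replicate differences with MLC901 at 12 h (-0.181) and at 8 h (-0.0675 untreated, -0.291 with MLC901) followed that excess less. The ND2 difference between MLC901 and untreated cells followed it more, at -0.54 at 12 h and at -0.53 at 8 h, where the same untreated samples enter both sides. A bias linked to gene length may account for the pattern: the 12 h difference correlated with gene span at rho = -0.383, against 0.0594 at 4 h, 0.00192 at 24 h, -0.244 at 8 h and -0.123 at 0 h. It was computed on the 72.3% of tested genes that have a span, or 87.6% of those called, and it does not tell length itself from a class of long genes. An effect of MLC901 in ND2 and not in ND1 also stays open, although limma called 0 genes for that difference, with 2075 at an unadjusted p under 0.05.

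Reduced-medium values did not match the symbols of their table. Another gene order in these columns may be the source, since a run of 500 entries matched ND2 at r = 0.991 after 1 constant shift. Another cell type, the medium or poor RNA was argued against: the 34 ribosomal protein genes, abundant in every human cell, had a median percentile of 57.7 among all entries in the reduced medium and of 99.5 in ND1 and ND2. No biological explanation was tested beyond that.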

How the results depend on the processing

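Offsets of 4 and 50, joint quantile normalization, averaged ND2 replicates, the trended robust prior, removal of the 8 h and 12 h samples of ND2, 1 experiment term per time and the MLC901 arm were tried after seeing the data. Over all alternatives except leave-outs, 202 gene counts stayed within 1.5 times the reported count and 49 moved, and of list counts 166 stayed and 36 moved. A count of 0 that stayed 0 was taken as unmoved, and every reported MLC901 gene count was 0. Named genes kept direction and their called or uncalled state in 6565 instances, lost the call in 1035, gained it in 21 and turned direction in 5. The 6565 include MLC901 genes of smallest p, which had no call to lose. Leave-outs moved 28 of the gene counts and 25 of the list counts, and ended 899 calls of named genes. Joint normalization moved none of these counts. A replicate block gave 0 genes for MLC901 in each medium, 1081, 4273, 2978 and 2580 for the time course, and 807 for reduced 24 h minus 4 h. Replicate numbers did not pair samples (median correlation of replicate differences -0.0176 in ND2 and -0.00185 in NDb), so the fit without block was kept. On each array 23.4% to 24.4% of values lay below 0, and genes near background have compressed folds. Not run were normalization from unnormalized values in its variants, filters on detection p, a slide block and per-probe counts. Without series NDb-3 or NDb-4 no residual degrees of freedom are left. A left-out sample leaves 1 sample in a reduced condition, assumed to vary like the other groups. Causes were not tested except where fewer samples or a stricter criterion is the alternative itself.

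For MLC901 in the optimized medium, array weights gave 642 genes at 8 h, 1537 at 12 h and 55 over the mean. ND2 only gave 1 gene at 8 h and 1419 at 12 h, with 2 lists at 8 h and 3 over the mean. With 1 experiment term per time 2 genes were called over the mean (LOC100132673, adjusted p = 0.0211, and LOC440063, adjusted p = 0.0365) and 3 lists. No filter on level gave 1 gene at 0 h, 3 at 8 h, 1 at 12 h and 3 lists over the mean. Values under 1 set to 1 gave 1 gene at 24 h and 1 for the mean minus 0 h. Lists called at 8 h were 0 with ND1 arrays singly with duplicateCorrelation (correlation 0.255), ND2 replicates averaged, no experiment term, offset 4, an estimated correlation, fry, and without the 8 h and 12 h samples of ND2, and 2 above background on all arrays. Lists at 12 h were 0 with an estimated correlation, fry and without the 8 h and 12 h samples of ND2, and 1 with ND2 replicates averaged. Lists over the mean were 0 with these 4 settings, 3 with all experiments in 1 fit and 2 with offset 50.

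For the untreated time course at 4, 8, 12 and 24 h, counts with at least 1.5-fold were 349, 1032, 826 and 848, with no experiment term 192, 851, 533 and 562, and with ND2 replicates averaged 271, 1204, 1072 and 1305. At 4, 8 and 12 h, 1 experiment term per time gave 1762, 7489 and 4969, and array weights 1881, 7207 and 7102. ND2 only gave 6616 at 8 h. Without the 8 h and 12 h samples of ND2, 628 and 790 genes were called at 8 and 12 h, each arm then being 1 ND1 sample with its spread taken from other groups. Of the named genes, 5 had the other sign at 8 h in that setting, all at values near 0 and none called (TXNRD1, adjusted p = 0.874, was the lowest): TXNRD1 (-0.068), SQLE (-0.017), RPL13 (0.036), RPL14 (0.035) and UQCRB (0.05). Lists called were 12, 15, 14 and 13 with fry, and 2 at 8, 12 and 24 h with an estimated correlation. At 8 h 5 lists were called with duplicateCorrelation, ND2 replicates averaged and the MLC901 arm, and 4 without the 8 h and 12 h samples of ND2. All experiments in 1 fit gave 10 lists at 4 h, 1 experiment term per time 12 at 12 h, and no experiment term 4 at 24 h.

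The fit of all experiments together pools values of NDb, ND1 and ND2 that could not be tied to the same gene. Its counts therefore decide nothing in either medium. For the reduced medium, it gave 160, 126, 345 and 265 entries for MLC901 at 4, 8, 12 and 24 h, 146 over the mean and 2197 for 24 h minus 4 h. The latter was 1546 above background on all arrays, 1625 with array weights, 1698 with the trended robust prior and 581 with at least 1.5-fold. At 12 h the robust prior, offset 4 and values under 1 set to 1 gave 1 each, and the last pair also 1 over the mean. No filter on level gave 8 at 12 h and 6 at 24 h.

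With each replicate series or sample left out, gene counts for MLC901 ranged from 0 to 0 at 0, 4 and 24 h, over the mean and for the mean minus 0 h, 0 to 1 at 8 h and 0 to 1419 at 12 h. Time course counts ranged from 193 to 1248 at 4 h, 757 to 6616 at 8 h, 704 to 4548 at 12 h and 964 to 2766 at 24 h. Reduced-medium counts ranged from 0 to 0 at 4 and 8 h, 0 to 23 at 12 h, 0 to 1 at 24 h and 141 to 306 for 24 h minus 4 h. List counts for MLC901 ranged from 0 to 1 at 0 and 4 h, 0 to 3 at 8 h, 12 h and over the mean, 0 to 2 at 24 h and 0 to 0 for the mean minus 0 h. Time course list counts ranged from 5 to 8 at 4 h, 4 to 10 at 8 h, 4 to 9 at 12 h and 5 to 10 at 24 h.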

Other observations

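The test of the share of risen mesenchymal genes was chosen after the result was seen, and the other tests in this part were written before.

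Among lists that camera did not call at 24 h (adjusted p between 0.1 and 0.884), several held members that moved far in opposite directions. Of 33 hypoxia and glycolysis genes 5 rose and 4 fell (6 and 4 adjusted over the list alone): the vasodilator peptide gene ADM rose 3.22-fold (SE 0.208) and NDRG1 1.91-fold (SE 0.130), while the glucose transporter gene SLC2A1 was 2.38-fold lower (SE 0.132). Of 16 neurotrophin and receptor genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), and VGF, a nerve growth factor inducible neuropeptide gene, fell by 1.71 (SE 0.133). Of 21 BMP and TGF-beta targets 5 rose and 5 fell (6 and 7 adjusted over the list alone), with the BMP antagonist gene NOG at -1.13 (SE 0.137) and the homeobox gene MSX1 at -1.12 (SE 0.144). Of 9 hedgehog genes 2 rose and 2 fell by either count, with GAS1, a co-receptor gene, at 1.38 (SE 0.136) and HHIP, a hedgehog-binding inhibitor gene, falling to 4.48, with 1 of 4 arrays above background. Of 19 FGF and ERK feedback genes 3 rose and 4 fell by either count, with FGFR3 2.67-fold higher (SE 0.204) and the phosphatase gene DUSP5 at -0.80 (SE 0.159). Of 12 metallothionein and metal response genes 1 rose and 5 fell (2 and 6 adjusted over the list alone); MT1X had -1.10 (SE 0.254), with -0.16 in ND1, and its call was lost without ND2-1 (adjusted p = 0.163) or ND2-2 (adjusted p = 0.162).

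The other lists that camera did not call at 24 h follow, with bracketed pairs giving counts up and down adjusted over the list alone. Neural crest genes had 3 of 14 up and 1 down (4 and 1 adjusted over the list alone), among them ETS1, 1.83-fold higher (SE 0.124). Synapse and excitability genes had 2 of 19 up and 2 down (2 and 5 adjusted over the list alone), and GAD1, the gene of a GABA-synthesising enzyme, was at least 1.37-fold lower. With no experiment term the calls of SLC2A1 (adjusted p = 0.0738), MSX1 (adjusted p = 0.111), ETS1 (adjusted p = 0.235), FGFR3 (adjusted p = 0.558) and MT1X (adjusted p = 0.59) were lost. Notch pathway genes had 4 of 19 up and 1 down (6 and 3), and mesoderm, blood and endothelial genes 0 of 6 up and 2 down (1 and 2 adjusted over the list alone). Endoderm and epithelial genes had 0 of 7 called (2 up adjusted over the list alone), S phase genes 1 of 28 up and 1 down (1 and 0), and NRF2 genes 2 of 26 up and 2 down by either count. ER stress genes had 0 of 32 up and 7 down (1 and 7), heat shock genes 6 of 21 up and 2 down by either count, and p53 targets 1 of 24 up and 2 down by either count, with TP53INP1 1.78-fold higher (SE 0.152). Aryl hydrocarbon receptor genes had 1 of 10 up and 3 down (2 and 3), CYP1B1 being the farthest. Histones had 2 of 20 up and 1 down by either count, pluripotency genes 0 of 10 up and 1 down by either count, and cholesterol synthesis and ribosomal protein genes 0 of 29 and 0 of 34 called by either count.

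The rise of matrix and contractile genes from 0 h to 24 h was set against the share of cells and the experiments. A difference between the experiments was argued against as its source, since the lower of the ND1 and ND2 list medians was 0.825, with 1.08 in ND1. A larger share of mesenchymal-like cells may account for the rise and cannot be told apart from a change within the progenitors. Of the tested members 77.8% rose (14 of 18) and 0 fell, between the bounds set for and against a larger share. No value of that percentage could have decided, since either would raise these genes in RNA of all cells together. Differentiation itself stays open as untested.

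For each comparison of 3 against 3 samples there are 10 splits, too few for a share under 0.05. For MLC901 at 0, 4, 8, 12 and 24 h the real count was 0 genes, which each of the 10 splits reaches by necessity; the highest other counts were 0, 1, 2157, 0 and 0. The split with 2157 set both ND1 samples at 8 h and the MLC901 sample of ND2-1 against the rest, which points to a structure of the samples by experiment. For 4, 8, 12 and 24 h minus 0 h the real counts of 1112, 4393, 3083 and 2663 were reached by 1 split, the real one, with highest others of 0, 1195, 1 and 0.

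Over the mean of 4 to 24 h, 100 splits were drawn. For genes called after adjustment the real count was 0, which all 100 reach by necessity, so they decide nothing (highest other 1). The same applies to the mean minus 0 h (100 splits; highest other 1) and the reduced medium (100 splits; highest other 3). The 1115 genes at an unadjusted p under 0.05 were reached by 2 of the 100 splits, the real one and 1 with 1177, a share under 0.05. Few splits thus reached that number. The share comes from 1 of several split tests and is not adjusted for them, so it does not exclude chance. The mean effects of ND1 and ND2 did not agree across genes (r = -0.00972, permutation p = 0.79). Chance was also not excluded for the 1 list called over the mean, which 32 splits reached with a highest other of 5. The same holds for the 846 reduced-medium entries at an unadjusted p under 0.05, which 43 splits reached with a highest other of 1840.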
